A study of Mus musculus with 4 samples.

How the data were processed

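The libraries were made from J1 mouse embryonic stem cells, a line derived from the inner cell mass of 129-strain blastocysts, grown without feeder cells. ATAC-seq uses the Tn5 transposase to cut and tag open DNA, so reads pile up where chromatin is accessible. The labels' protocols name the TruePrep DNA Library Prep Kit V2 for the libraries. There were 2 control libraries and 2 libraries from cells overexpressing Zscan4 (Zscan4 OE). The labels do not say whether the replicates of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

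The deposited table gives 1 value per gene and library for 46406 rows, named by gene symbol. Per the submitters' processing notes, Trimmomatic, Bowtie2 and featureCounts were used with build mm10. Their versions, the read filters, the treatment of duplicate and mitochondrial reads, any shift of read ends for the Tn5 cut site, and the gene annotation are not given in the sources used here. The values are called RPKM per the labels, that is, reads scaled by the feature's length and the library's total. The feature lengths recovered below had a median of 4336 bp over 15228 protein-coding genes with 20 reads or more, against a median annotated span of 24997 bp. The median gene's recovered length was 17.4% of its span, and 5.14% of these genes reached at least 90% of theirs. A value is therefore taken to cover exons and to leave out most introns, promoters and distal elements, though the lengths were not compared with exon models.

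The deposited RPKM values are not on 1 scale per library. Each value equals a whole number of reads divided by the feature length and by a library total, times the constant of the unit. That total was not the library's own: 8 totals took turns from row to row in genome order and from column to column, as happens when a vector of totals is recycled down the rows of a matrix. The totals were found from 2444 short RNA genes of known length. Each of the 8 stood behind 251 to 281 values of a single read, and the ninth most frequent candidate behind 5. All 38361 rows with 2 or more values above 0 gave whole reads and a whole length for exactly 1 of the 8 rotations, within the rounding of the 9 decimals or 10 significant digits printed in the table. Another 5918 rows had 1 value above 0, of which 722 allowed more than 1 rotation and were given the shortest length. The remaining 2127 rows were 0 throughout. Neighbouring genes stood 1 step apart in the rotation in 62.4% of 28666 pairs, against 12.5% for a rotation unrelated to position. Recovered reads and lengths are the smallest whole numbers that give the values, and both can be too small by a common factor. In 1131 short RNA genes with 2 or more values the recovered length was the annotated length in 86.7%. In simulated tables with known answers 8 of 8 totals and 100% of rotations were found, and 97.44% of lengths.

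Which total belonged to which column was not given in the sources used here. Only the 8 placements that keep the totals in the order of the rotation were compared. Among these, the one with the share of reads on exons most alike between libraries was taken. Placements out of that order were not tried. That assignment gave shares of 12.4% and 9.4% in the controls and 12.8% and 9.9% in Zscan4 OE, a ratio of 1.36 between the highest and the lowest. The 7 other placements in rotation order gave ratios from 4.17 to 10.15. It also places the control total first at the first gene of chromosome 1 in the table. Each value was then multiplied by the total used and divided by the library's own total, and RPKM below means this rescaled value. What the other 4 totals stand for is not given in the sources used here.

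The plan fixed before the data were examined took the values as RPKM scaled by library. Since they were in another unit, the planned test was kept and run on the rescaled values, and the values as deposited became an alternative. The test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.1), with an eBayes trend and no covariate, for rows with a mean RPKM of at least 0.1. Both directions were tested, with Benjamini-Hochberg adjustment over all tested rows and a threshold of 0.05. A log2 difference is on this scale and understates the change of genes with low values. Of the symbols, 33703 (72.6%) matched the RefSeq annotation of GRCm38, the assembly behind mm10, from which coordinates and chromosomes were taken. More than 1 row carried the same symbol for 80 symbols.

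Before the data were examined 24 gene lists were fixed, and 22 had at least 5 tested members. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Camera sets a list against the other genes, while fry tests it against no change. Summed reads of a list are given as RPM, reads divided by the library total and multiplied by 1000000, with exact Poisson 95% intervals that cover counting error only. Genes were named by a rule fixed in advance. In each direction it took the 12 largest log2 differences past the threshold with non-overlapping groups, or, where none passed, the 10 non-overlapping rows with the largest moderated statistic. It added tested members of the Zscan4 cluster, the 2 members of each list with the largest statistic, and 11 genes fixed by name. Other named genes were chosen after their values were seen and are said to be.

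Depth limited the test. Recovered exon reads numbered 131205 and 272368 in the controls and 461681 and 486528 in Zscan4 OE, and the median row held 1, 3, 4 and 5 reads. The test was run on simulated reads with 200 changed genes. The reads were drawn from each gene's rate pooled over the 4 libraries, scaled by each library's exon reads, with gamma noise of shape 10. Differences between replicates that move whole groups of genes together were not simulated, so these rates hold for that setting only. Over 40631 simulated rows with no minimum of reads the test recovered 0% of 98 genes changed 4-fold and 0% of 100 changed 16-fold, and called 0 unchanged genes. Over 18913 simulated rows with 20 reads or more it recovered 3.1% of the 4-fold and 75% of the 16-fold changes, and called 9 unchanged genes. A minimum of 20 reads was therefore added as an alternative after seeing the data, together with voom (limma) on the recovered reads.

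Other alternatives were pseudocounts of 0.01 and 1, no filter, a minimum mean RPKM of 1, libraries centred on their medians, quantile normalization, eBayes without trend and robust, the replicate number as a block, leaving out each library in turn, and an adjusted p under 0.1. Scaling by recovered exon reads was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest. GC content was not checked, since no genome sequence was used here.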

Results

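Chromatin accessibility over gene exons was measured by ATAC-seq in J1 embryonic stem cells, in 2 control libraries and 2 libraries with Zscan4 overexpression. Zscan4 is a zinc finger protein made in 2-cell embryos and, briefly, in a small share of embryonic stem cells. The series title links it to loss of a co-repressor complex and a gain of accessibility, so the comparison asks which genes became more or less accessible. The libraries were shallow. Their totals were 1061428 and 2903602 reads in controls 1 and 2, and 3605774 and 4899494 in Zscan4 OE 1 and 2. Exon reads made up 10.9% ± 2.11 (SD, n = 2) of the control totals and 11.4% ± 2.03 (SD, n = 2) of the Zscan4 OE totals. The assignment of totals to libraries was chosen to make these shares alike. A gene without reads was listed at 0, and 3 reads, the one-sided 95% limit that a count of 0 allows for counting error, correspond to 2.83, 1.03, 0.832 and 0.612 RPM in the 4 libraries in that order. Replicates differed by more than sampling noise, with a chi-square over its degrees of freedom of 2.33 between the controls and 1.91 between the Zscan4 OE libraries. Across 19011 genes with 20 reads or more, which are not independent, Pearson's r of log2 values was 0.52 between the controls, 0.79 between the Zscan4 OE libraries and 0.60 to 0.65 between a control and a Zscan4 OE library. Over all tested genes it was 0.33, 0.31 and 0.23 to 0.37, so the order of these pairs depended on the genes taken.

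**Figure D1:**
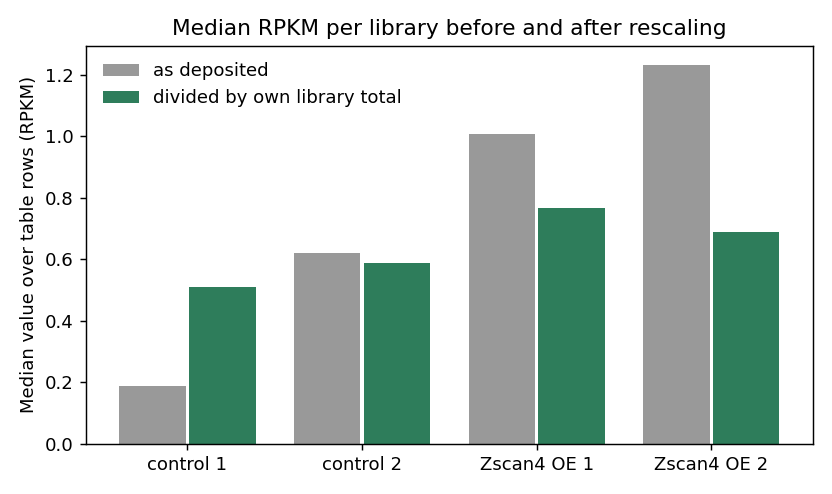
Median value over all table rows in each library, in RPKM, as deposited (grey bars) and after each library was divided by its own total (green bars). The deposited medians run from 0.189 to 1.232 and the rescaled medians from 0.51 to 0.767.

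The overexpressed gene could not serve as a check of the labels. The table holds 8 members of the Zscan4 cluster on chromosome 7, and 6 of them (Zscan4a, Zscan4c, Zscan4d, Zscan4e, Zscan4f and Zscan4-ps3) were listed at 0 in all 4 libraries. The pseudogene Zscan4-ps1 (chromosome 7, 11065139 to 11069691, GRCm38) had 1 read in control 1, 0 in control 2 and 1 in each Zscan4 OE library. Zscan4-ps2 had 1 read, in Zscan4 OE 1. The members are near-identical copies, and the number of reads the authors' counting set aside because they matched several copies is unknown.

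No gene passed the threshold in either direction. Of 42989 genes tested with limma, 0 were higher and 0 lower in Zscan4 OE at an adjusted p under 0.05, and the smallest adjusted p was 0.156. At an unadjusted p under 0.05 there were 2189 higher and 573 lower genes, 6.4% of those tested. Non-overlapping groups were found in 8409 genes with higher and 4354 with lower values in Zscan4 OE, 29.7% of all. Chance gives 33.3% only where values do not tie. Ties at 0 were common, with 35.8% and 20.1% of tested genes at 0 in controls 1 and 2, and 14.5% and 11.2% in Zscan4 OE 1 and 2. The median log2 difference was 0.28, and it ran from 1.25 in genes with 1 to 4 reads to 0.11 in genes with 100 or more, while summed reads per library total differed 1.01- to 1.06-fold in each range of reads. Of the genes at an unadjusted p under 0.05, 79.3% were higher. Centring each library on its median took that share to 67.5% and the median difference to 0.00. The share was 60.9% with quantile normalization and 97% in the values as deposited, where 0 genes passed. Leaving out Zscan4 OE 1 gave 4530 higher and 6 lower genes, and leaving out Zscan4 OE 2 gave 3889 and 2. In each of these fits 100% of the higher genes had 0 reads in both controls, and without either control the counts were 0.

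The rows with the strongest statistics were short features with few reads, and none passed the threshold (adjusted p = 0.156 for each, limma). The 10 with higher values were absent from both controls. They were the D segments Ighd5-1 and Trdd2 with 1 read in each Zscan4 OE library, the small RNA genes Gm23411 (3 and 4 reads), Mir6999 (2 and 4) and Gm23344 (2 and 3), the pseudogenes Gm18620 (8 and 7) and Gm25148 (6 and 5), the long non-coding gene Gm3625 (2 and 2), Gm22933 (3 and 3) and Gm23130 (2 and 3). The 10 with lower values had 0 reads in both Zscan4 OE libraries and 1 to 4 in each control. They were Mir7077, Mir6969, Mir652, Mir7660, Traj2, Gm22534, Gm25991, Gm26280, Gm25666 and Gm24517. Mir7660 (chromosome 6, 115775657 to 115775719, GRCm38) had 2 reads in each control, and Mir7077 (chromosome 8, 117453023 to 117453079) had 1 and 3.

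Among the 19011 genes with 20 reads or more, a filter chosen after seeing the data, limma called 4 genes higher and 1 lower. On simulated reads with 200 changed genes this setting called 9 unchanged genes, beside 75% of the 100 changed 16-fold. Reads without changed genes were not simulated, so 9 is not the number of false calls to set against these 5. With the replicate number as a block at the same filter 0 genes were higher and 0 lower. The 5 genes are named here after their values were seen. Calm5, a calmodulin-like gene on chromosome 13 (3854173 to 3854761, GRCm38), had 0 reads in both controls and 6 and 14 in Zscan4 OE 1 and 2 (adjusted p = 0.00254). Npm3, a nucleoplasmin-family histone chaperone gene on chromosome 19 (45747734 to 45749565), had 0 reads in both controls and 9 and 15 (adjusted p = 0.0249). The pseudogenes Gm4052 (0, 0, 10 and 10 reads in the 4 libraries, adjusted p = 0.000848) and Gm2791 (0, 0, 13 and 7 reads, adjusted p = 0.00254) followed the same pattern. Gm6989, a pseudogene on chromosome 12, was the lower one, with 5 and 18 reads in the controls and 0 and 1 in Zscan4 OE (adjusted p = 0.0118). With voom on the same genes 0 were higher and 1 was lower, Gm10801 (adjusted p = 0.00551), and at an unadjusted p under 0.05 voom gave 636 higher and 339 lower. Leaving out a control decided these counts. Without control 1 they were 466 higher and 69 lower, and without control 2 they were 800 and 181. Without Zscan4 OE 1 they were 5 and 2, and without Zscan4 OE 2 they were 27 and 2.

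Genes of the 2-cell stage, the program Zscan4 belongs to, had few reads in every library and a larger share of reads in Zscan4 OE. Their summed exon reads were 24.5 RPM in control 1 (95% interval 16 to 35.9, 26 reads) and 25.1 in control 2 (19.7 to 31.6, 73 reads). In Zscan4 OE they were 36.9 (30.9 to 43.7, 133 reads) and 35.9 (30.8 to 41.6, 176 reads). The group means, 24.8 ± 0.457 and 36.4 ± 0.681 (SD, n = 2), differed 1.47-fold, more than the spread between replicates. That spread was narrower than counting error, and the interval of control 1 overlapped those of both Zscan4 OE libraries. Zfp750, Patl2 and Pramel6, the 3 members that differed most, held 69.9% of the difference, and without them the ratio was 1.17. Divided by exon reads instead of library totals, the ratio was 1.39 and the lowest Zscan4 OE value was 1.07 times the highest control value. Of 23 lists with reads 3 had non-overlapping sums, where chance gives 33.3% of lists. The test across genes did not single the list out. The list was fixed with 51 members, of which 31 were in the table, 25 had any read and 18 were tested. Of these 18 members 14 had a positive and 4 a negative log2 difference, with a median 0.25 above that of all genes (camera adjusted p = 0.971, and 0.982 with an estimated correlation). Tested against no change instead of against the other genes, the fry adjusted p was 0.506. The median relative to all genes was 0.05 with quantile normalization and 0.65 with voom at 20 reads or more. It was 0.46 without control 2, 0.51 without Zscan4 OE 1, 0.23 without control 1 and 0.17 without Zscan4 OE 2. None passed over all genes, and 0 did when adjusted over the list alone. Zfp750, an epidermal differentiation factor gene on chromosome 11 (121510976 to 121519342, GRCm38), was at 0.266 ± 0.377 RPKM in controls and 1.31 ± 0.0276 in Zscan4 OE (SD, n = 2), from 0, 5, 15 and 21 reads. Pramel6, a PRAME-family gene on chromosome 2, was at 0.474 ± 0.0309 and 1.2 ± 0.38 RPKM (SD, n = 2), from 1, 3, 7 and 15 reads. Zfp352, a gene of the 2-cell stage, had 1, 1, 1 and 0 reads, and Tcstv1 and Tcstv3 were not among the tested genes.

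**Figure D2:**
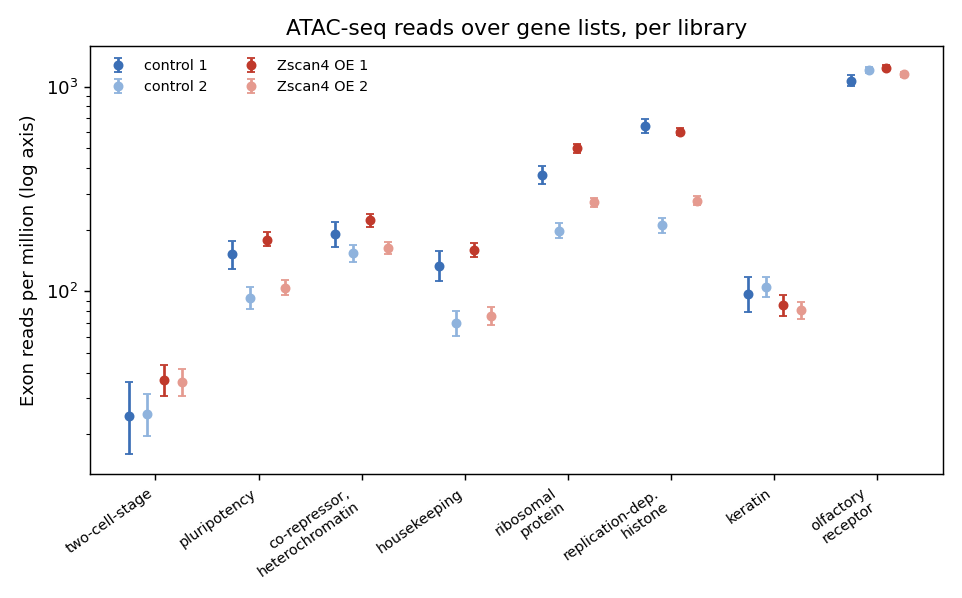
Summed exon reads, in RPM, over 8 gene lists, on a log axis, 1 point per library with its exact Poisson 95% interval. Reads of 2-cell-stage genes were 24.5 and 25.1 RPM in the controls and 36.9 and 35.9 in Zscan4 OE, while housekeeping reads split the replicates of each group.

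The genes of co-repressors and heterochromatin proteins, the machinery the title names, showed no change in their own accessibility that this test could detect. Of 25 tested members 14 had a positive and 11 a negative difference, and 0 passed over all genes or adjusted over the list alone. Their median lay at −0.04 relative to all genes (camera adjusted p = 0.971), at 0.01 with quantile normalization and at 0.18 as deposited. It was −0.24 without Zscan4 OE 1, −0.14 without control 2, −0.07 without Zscan4 OE 2 and −0.03 without control 1. Summed reads were 190 and 153 RPM in the controls and 222 and 163 in Zscan4 OE, so the groups overlapped. Trim28, the KRAB zinc finger co-repressor, was at 1.96 ± 0.431 RPKM in controls and 2.71 ± 0.784 in Zscan4 OE (SD, n = 2). Kdm1a, a histone H3 lysine demethylase, was at 1.202 ± 0.101 and 1.06 ± 0.324, and Hdac1, a histone deacetylase, at 1.32 ± 0.453 and 1.86 ± 0.448 (SD, n = 2). The members with the largest statistics were Dnmt3l, a cofactor of DNA methylation, with a log2 difference of 0.99 (SE 0.446) and Rcor1, a partner of Kdm1a, with −0.85 (SE 0.641). Their adjusted p was 0.869 each (limma).

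Pluripotency genes had a mean above that of all rows in each library. Their 24 tested members averaged 2.15 and 1.28 RPKM in the controls and 2.76 and 1.49 in Zscan4 OE, against 1.32, 0.956, 1.42 and 1.024 over all rows. The co-repressor list was also above, at 1.38, 1.12, 1.65 and 1.18. Of these members 15 had a positive and 9 a negative difference, and the median equalled that of all genes (0.00, camera adjusted p = 0.971; −0.08 as deposited). It depended on the libraries kept, at 0.34 without control 1, −0.27 without control 2, −0.17 without Zscan4 OE 1 and 0.21 without Zscan4 OE 2. Pou5f1 was at 2.50 ± 1.80 RPKM in controls and 1.90 ± 1.15 in Zscan4 OE, and Nanog at 1.09 ± 0.240 and 1.66 ± 0.802 (SD, n = 2). Dppa3, a maternal-effect gene, had 4.66 RPKM in Zscan4 OE 1 and 0.686 in Zscan4 OE 2, on either side of 1.06 and 0.772 in the controls. Tdgf1, a Nodal co-receptor, had a log2 difference of 1.201 (SE 0.518) and Dppa4 of 1.63 (SE 0.704), with 2, 11, 25 and 30 reads and 1, 3, 22 and 9 reads in the 4 libraries. Their adjusted p was 0.869 each (limma).

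Lineage genes that embryonic stem cells keep largely silent did not pass either. Relative to all genes the medians were −0.26 for 17 primitive endoderm genes (camera adjusted p = 0.625), 0.01 for 15 trophectoderm genes (0.971), −0.25 for 13 mesoderm genes (0.902) and −0.40 for 14 neuroectoderm genes (0.538). The last 2 turned to 0.29 and 0.20 without control 1, and stood at −0.575 and −0.73 without control 2. Trophectoderm genes were at 0.21 and −0.23 in these fits, and primitive endoderm genes at −0.10 without Zscan4 OE 1. No member of these lists passed over all genes, and 0 did when adjusted over the list alone. Sox17, an endoderm regulator, was at 3.43 ± 0.458 RPKM in controls and 1.84 ± 0.36 in Zscan4 OE, and Otx2, a forebrain and epiblast factor, at 1.24 ± 0.139 and 0.621 ± 0.33 (SD, n = 2). Six3, another forebrain factor, was at 0.804 ± 0.331 and 0.271 ± 0.0945. Hand1, a trophoblast and heart factor on chromosome 11, was at 2.06 ± 0.251 and 0.946 ± 0.037, with adjusted p = 0.853 (limma). Krt18, an early trophectoderm keratin, had 0, 1, 6 and 9 reads, Msgn1 0, 1, 5 and 6, Mixl1 2, 2, 9 and 14, and Amn 2, 1, 5 and 18. Fibroblast genes, which would mark leftover feeder cells, had a median of −0.09 over 14 genes (adjusted p = 0.971), −0.27 without control 2 and 0.065 without Zscan4 OE 1, with 88.6 and 62.3 RPM in the controls and 95.7 and 71.6 in Zscan4 OE. Col3a1 was at 1.21 ± 0.0787 and 0.693 ± 0.0983 RPKM (SD, n = 2), and S100a4 had 0, 1, 2 and 2 reads.

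Germline, telomere, imprinted and housekeeping genes were alike in giving no call. Their medians relative to all genes were 0.15 for 18 germline genes, 0.13 for 14 telomere and recombination genes, −0.07 for 20 imprinted genes and 0.03 for 16 housekeeping genes (camera adjusted p = 0.971, 0.971, 0.971 and 0.996). Under quantile normalization the germline median was −0.16 and the imprinted median 0.07, and in the values as deposited the telomere and housekeeping medians were −0.09 and −0.13, so these lists had no set direction. Without control 2 the medians were −0.44 for housekeeping, −0.41 for imprinted, −0.21 for telomere and 0.08 for germline genes, and without control 1 they were 0.16, 0.12, 0.31 and −0.15. Housekeeping genes stood at −0.40 without Zscan4 OE 1 and 0.45 without Zscan4 OE 2. Hormad1 and Taf7l, genes of meiosis and spermatogenesis, had 2, 3, 0 and 1 reads and 4, 12, 7 and 5 reads. Spo11, the meiotic double-strand break enzyme, had 1, 3, 13 and 14 reads, and Terf1, a telomere-binding protein gene, was at 1.04 ± 0.32 RPKM in controls and 2.03 ± 0.142 in Zscan4 OE (SD, n = 2; limma adjusted p = 0.869). Peg10, a paternally expressed gene, was at 0.374 ± 0.129 and 1.25 ± 0.345 RPKM (SD, n = 2), and H19 had 0, 1, 4 and 5 reads. Among housekeeping genes Actb was at 2.05 ± 1.08 and 2.88 ± 1.92 RPKM, Gapdh at 4.97 ± 2.32 and 4.98 ± 2.92, Hprt at 0.766 ± 0.05 and 1.76 ± 0.25, and Gusb at 0.652 ± 0.0425 and 1.46 ± 0.35 (SD, n = 2).

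Of the gene families, microRNA and defensin genes passed the preset test, and both calls were lost in other fits. The 877 microRNA genes had a median 2.08 above all genes (camera adjusted p = 0.00206), and the 46 defensin genes 1.33 above (adjusted p = 0.00206). With an estimated correlation the adjusted p was 0.982 for each. That test had 2 residual degrees of freedom and so little power over 22 lists. The estimated correlation of defensin genes was −0.001, below the preset 0.01, so correlated members do not explain the loss of their call. Tested against no change, which is another question, the fry adjusted p was 0.779 and 0.506. No member passed over all genes, while 155 microRNA and 2 defensin genes did when adjusted over the list alone. Such calls can rest on very few reads. The 2 microRNA genes with the largest statistic, Mir7077 and Mir6969, had 1 and 3 and 1 and 2 reads in the controls and 0 in Zscan4 OE. As deposited the camera adjusted p was 0.759 and 0.422. Leaving out control 1 gave medians of 2.065 for microRNA and 1.37 for defensin genes, and leaving out control 2 gave 2.32 and 1.92. The medians were 1.136 and 1.097 without Zscan4 OE 1, and 1.397 and 1.537 without Zscan4 OE 2. They also followed the pseudocount, at 0.812 and 0.316 with 1 and at 3.656 and 2.854 with 0.01. MicroRNA genes with 20 reads or more had a median at 0.01 (adjusted p = 0.623). They passed there without control 1 (0.32, adjusted p = 7.9e-05) and without Zscan4 OE 2 (0.26, 0.000395), though not with an estimated correlation (adjusted p = 0.965 and 0.87). Too few defensin genes had as many. Summed microRNA reads overlapped between groups, with 273 and 202 RPM in the controls and 333 and 208 in Zscan4 OE. Summed defensin reads did not, with 13.2 and 12.1 RPM, from 14 and 35 reads, against 20 and 18.8 RPM, from 72 and 92 reads. Defb44-ps had 0, 0, 8 and 6 reads and Defb14 had 0, 0, 3 and 2.

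The other families gave no call in the preset test. Relative to all genes the medians were 0.02 for 1148 olfactory receptor genes, −0.03 for 256 vomeronasal receptor genes, −0.07 for 345 numbered zinc finger genes, −0.07 for 65 replication-dependent histone genes and −0.23 for 13 Rhox genes (camera adjusted p = 0.971 each). They were −0.28 for 40 Hox genes and 0.14 for 83 ribosomal protein genes (0.625 each), and −0.37 for 50 keratin genes (0.542). Olfactory receptor genes turned to −0.27 as deposited (adjusted p = 0.422) and to −0.58 with quantile normalization (adjusted p = 1.9e-05), where vomeronasal receptor genes stood at −0.55 (adjusted p = 0.0103). In that fit the adjusted p was 0.66 for each with an estimated correlation. Histone genes turned to 0.66 without control 1 (adjusted p = 0.0317, and adjusted p = 0.991 with an estimated correlation) and stood at −0.79 without control 2 (adjusted p = 0.0157, and 0.92 with an estimated correlation). At 20 reads or more olfactory receptor genes stood at −0.28 without control 1 (adjusted p = 0.00204) and 0.33 without control 2 (0.00158), and histone genes at 0.72 (1.1e-06) and −0.53 (0.00563). Histone genes were at 0.48 there without Zscan4 OE 2 (0.00154). With an estimated correlation the adjusted p was 0.965, 0.985 and 0.87 in these fits in that order. Without control 1 and control 2 the medians were 0.66 and −0.85 for Rhox genes, −0.255 and 0.63 for vomeronasal receptor genes and 0.115 and −0.23 for zinc finger genes, and Hox genes were at 0.03 without Zscan4 OE 2. Ribosomal protein genes passed with quantile normalization, at 0.44 (adjusted p = 0.00441), as deposited (0.0222), at 20 reads or more (0.00353), there with voom (0.00481), without control 1 (0.0317) and without Zscan4 OE 2 (0.0244). With an estimated correlation the adjusted p in these fits was 0.927, 0.993, 0.971, 0.959, 0.991 and 0.893, a test left with 2 residual degrees of freedom, or 1 where a library is left out. At 20 reads or more they also passed without control 1 (0.55, adjusted p = 4.77e-06) and without Zscan4 OE 2 (0.67, 2.96e-07), where the adjusted p with an estimated correlation was 0.965 and 0.87, and were at 0.29 (0.365) and 0.04 (0.486) without control 2 and Zscan4 OE 1. The ribosomal median was −0.03 without control 2 and −0.12 without Zscan4 OE 1. No mitochondrially encoded gene was in the table. Keratin reads were 97 and 105 RPM in the controls and 85.4 and 80.6 in Zscan4 OE, 0.823 times the control mean. Keratin genes passed at 20 reads or more (−0.41, adjusted p = 0.0402), there with voom (−0.77, 0.00741), there without control 1 (−0.77, 0.000212) and, at the planned filter, without Zscan4 OE 2 (−0.38, 0.0435), and stood at 0.03 without Zscan4 OE 1. With an estimated correlation the adjusted p in these 4 fits was 0.971, 0.959, 0.965 and 0.893. Hoxb1, a hindbrain patterning gene on chromosome 11 (96365746 to 96368254, GRCm38), was at 2.25 ± 0.253 RPKM in controls and 0.339 ± 0.142 in Zscan4 OE (SD, n = 2), with 6, 14, 2 and 5 reads. Its log2 difference was −2.46 (SE 0.527, limma adjusted p = 0.339). Zfp708, on chromosome 13, went the other way with 1, 1, 18 and 27 reads and a log2 difference of 2.69 (SE 0.609, adjusted p = 0.375). Members listed at 0 or 1 read in both controls were Zfp936 (9 and 11 reads in Zscan4 OE), Krt16 (2 and 8), Rhox1 (5 and 2), Rhox11-ps2 (7 and 1), Rpl10l (6 and 2), Hist1h2ba (1 and 1), Hist1h4k (3 and 3), Vmn1r-ps16 (2 and 2), Vmn2r-ps75 (1 and 4) and Olfr1007-ps1 (2 and 1). Hoxa10 had 0, 2, 15 and 12 reads, Rpl7 2, 10, 28 and 36, and Olfr1041-ps1 1, 1, 0 and 0.

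Reads from chromosome 11 made up a smaller share in Zscan4 OE. Shares are of the exon reads on rows matched to a chromosome, which were 87%, 86.8%, 87.5% and 87.7% of exon reads in the 4 libraries. The share was 9.25% in control 1 (Wilson 95% interval 9.08 to 9.42) and 9.43% in control 2 (9.31 to 9.54), and 7.37% and 7.26% in Zscan4 OE 1 and 2 (7.29 to 7.45 and 7.18 to 7.34). Of all exon reads it was 8.05% and 8.18% against 6.45% and 6.36%. The difference of the matched shares, −0.35 on the log2 scale, was 12.96 times the larger gap between replicates on this chromosome. That gap was only −0.027, between the controls. Elsewhere the gap between the controls reached 0.371, on chromosome 6, as wide as the shift on chromosome 11. The median log2 difference of the 2228 tested genes of chromosome 11 lay at −0.45 relative to all genes. Against the mean of the controls the chromosome's relative median was 0.06 and −0.06 in controls 1 and 2, and −0.36 and −0.43 in Zscan4 OE 1 and 2. Of 20 chromosomes 8 had non-overlapping shares, where chance gives 6.7, and in 4 of them the groups differed by more than the larger replicate gap. Besides chromosome 11 these were chromosomes 4, 14 and 16, with log2 differences of 0.07, −0.06 and −0.08. On other chromosomes a single library stood apart. Control 2 had 3.82% of its matched exon reads on chromosome 6, against 4.94%, 5.26% and 5.28% in control 1 and Zscan4 OE 1 and 2, and Zscan4 OE 2 had 5.55% on chromosome 3, against 4.59%, 3.97% and 4.64% in controls 1 and 2 and Zscan4 OE 1.

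**Figure D3:**
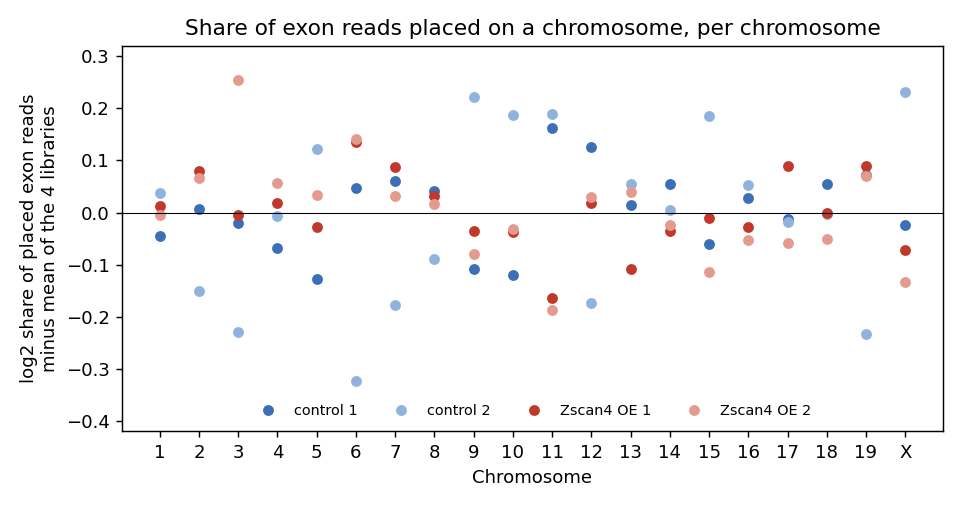
log2 share of each chromosome among exon reads on rows matched to a chromosome (placed exon reads), minus the mean of the 4 libraries, 1 point per library. On chromosome 11 the controls lie at 0.16 and 0.19 and Zscan4 OE at −0.17 and −0.19, while on chromosome 6 control 2 lies at −0.32.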

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

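The values as deposited, the scaling by exon reads, voom and every fit with a minimum of 20 reads were chosen only after the data had been seen. In the values below, list medians are relative to all genes, and the median of chromosome 11 is relative to the other chromosomes (−0.43). The counts of 0 higher and 0 lower genes held for both other pseudocounts, no filter, a mean RPKM of at least 1, centring, quantile normalization, scaling by exon reads, the values as deposited, both other eBayes settings and an adjusted p under 0.1. Depth limits these counts, since in the simulation the test recovered 0% of 16-fold changes without a minimum of reads.

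With a pseudocount of 0.01 the chromosome 11 median was −0.50. With a pseudocount of 1 it was −0.21, the median of all genes 0.10 and the co-repressor median 0.028. At a mean RPKM of at least 1 the medians of chromosome 11 and of all genes were −0.39 and 0.10, while Zscan4-ps1 and the 2-cell-stage list gave no value. Centred libraries had a median of 0.003 over all genes, by construction. Quantile normalization gave −0.037 for all genes, −0.38 for chromosome 11 and 0.009 for the co-repressor list. It took the number of other lists that passed from 2 to 5 and the olfactory receptor median to −0.58. With an estimated correlation 0 lists passed. In the values as deposited the median of all genes was 1.40, that of chromosome 11 −0.35 and that of the co-repressor list 0.18, Zscan4-ps1 stood at 1.17 and 1 list passed.

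Leaving out 1 library gave 0 to 4530 higher and 0 to 6 lower genes. The lone library of a group is then assumed to vary like the other group. With a Zscan4 OE library left out the spread came from the controls alone, where a gene at 0 in both has none, and all higher calls were such genes. The median of all genes ran from 0.12 to 0.36, chromosome 11 ran from −0.42 to −0.37, and 1 to 4 lists passed. Histone genes ran from −0.79 without control 2 to 0.66 without control 1. The cause of the other shifts was not tested.

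At 20 reads or more there were 4 higher and 1 lower genes, with medians of 0.14 for all genes, −0.39 for chromosome 11 and 0.10 for the co-repressor list. Voom gave 0 higher and 1 lower, 0.15 for all genes and 0.024 for the co-repressor list. Zscan4-ps1 gave no value in either. Leaving out control 1 there gave 466 higher and 69 lower genes, 5 lists, a chromosome 11 median of −0.39, an olfactory receptor median of −0.28 and a histone median of 0.72. Leaving out control 2 gave 800 and 181 genes, −0.074 for all genes, −0.39 for chromosome 11, 0.14 for the co-repressor list, −0.20 for microRNA genes, 0.33 for olfactory receptor genes and −0.53 for histone genes. The last 2 passed the test in both of these fits, in opposite directions. With an estimated correlation, run in every fit after the data had been seen, no list passed, and the smallest adjusted p was 0.155. That test had at most 2 residual degrees of freedom, so a call was hard to reach. Leaving out Zscan4 OE 1 gave 5 and 2 genes, 0 lists, −0.02 for all genes and −0.17 for microRNA genes. Leaving out Zscan4 OE 2 gave 27 and 2 genes, −0.37 for chromosome 11 and 0.48 for histone genes. The cause was not tested.

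The labels number the replicates without saying that a number marks a shared culture or day. The correlation of the deviations of same-numbered libraries was 0.04 over all tested genes and 0.13 at 20 reads or more, so the numbers were not taken to pair the libraries. Summed reads of some lists still split alike by number. Replicate 1 over replicate 2 was 1.91 in controls and 2.1 in Zscan4 OE for housekeeping genes, and 1.88 and 1.84 for ribosomal protein genes. For olfactory receptor genes it was 0.885 and 1.07. A factor shared by same-numbered libraries is therefore left open. With the replicate number as a block 0 genes were higher and 0 lower, with 1701 and 718 at an unadjusted p under 0.05. With the block at 20 reads or more the counts were 0 and 0, and the medians of all genes, chromosome 11 and the co-repressor list were 0.14, −0.39 and 0.10. There ribosomal protein genes (adjusted p = 0.00112) and keratin genes (0.027) passed as they did without the block, and the adjusted p was 0.944 for each with an estimated correlation.

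Among named genes 1208 values under the alternatives kept their direction and side of the threshold, 33 newly passed it, 27 turned direction without a call and 0 turned with a call. Among lists 321 kept both, 18 newly passed, 11 no longer passed, 87 turned direction without a call and 7 turned with a call in the main fit or the alternative.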

Other observations

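Of the tests here, those of the rotating totals, the copy number of chromosome 11, gene density and signal over background, and the removal of 3 genes from the 2-cell-stage list, were chosen only after the result was seen. The individual rows in the next paragraph were also picked after their values were seen.

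Some rows with the most reads differed between groups or between replicates. Gm10800, a predicted gene, was at 995 and 1893 RPKM in the controls and 351 and 719 in Zscan4 OE, 0.371 times the control mean. Gm10801 was at 260 and 172 against 34.7 and 51.8, 0.201 times. The sum of rows resembling mitochondrial genes, such as Gm10222 and Gm10925 side by side on chromosome 1, made up 0.964% and 0.297% of exon reads in controls 1 and 2, and 1.05% and 0.281% in Zscan4 OE 1 and 2. Histone reads followed the same split, with control 1 at 3.06 times control 2 and Zscan4 OE 1 at 2.17 times Zscan4 OE 2. Housekeeping genes gave 1.91 and 2.1, ribosomal protein genes 1.88 and 1.84, and olfactory receptor genes 0.885 and 1.07.

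The median value over genes was higher in Zscan4 OE than in controls, most in genes with few reads. The rotating totals are a candidate cause of most of this in the deposited values. The median log2 difference was 1.40 there and 0.28 once each library was divided by the total assigned to it. The totals were assigned to make exon shares alike, so this fall was in part built in and is no independent test. Unequal depth may account for most of what remained, as the mean log2 difference went from 0.45 to 0.12 when all libraries were thinned to the smallest total, and the microRNA median from 2.36 to 0.18, while the defensin median went only from 1.61 to 1.38 (0 to 2.47 over 20 draws). A rise in accessibility over all genes was not tested apart from these, because values within each library are shares of its own total.

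Chromosome 11 held a smaller share of reads in Zscan4 OE. A bias against gene-dense sequence would lower other gene-dense chromosomes too. On the 4 other most gene-dense chromosomes (7, 17, 19 and 2) the differences were 0.118, 0.031, 0.16 and 0.146, with a median of 0.13. None shared the fall of −0.35 on chromosome 11, but each was below the larger gap between replicates (0.21 to 0.93 of it). These values argue only against a bias that lowers such chromosomes as much as chromosome 11, and a weaker one was left open. For a copy number that differed between the cultures 3 criteria were tried after the data had been seen, and they gave 3 different answers: all 7 windows of 20 Mb were lower (−0.53 to −0.30), which it predicts; olfactory receptor genes, at 0.11 (counting SE 0.11), lay 0.499 from the other genes, over 2 SD (0.248) of that gap on other chromosomes, against it; and pseudogenes, at −0.28 (SE 0.093), lay near the chromosome, so it stays open, the more so as these 2 sets differed by up to 0.503 and 0.399 between replicates and the gap on chromosome 14 was −0.59. For a loss at active genes alone, genes were split into 3 levels of mean RPKM. The log2 difference was −0.28 (SE 0.049) at the lowest level, −0.358 at the middle and −0.365 at the highest. Middle-level shares were 7.91% and 8.75% in controls 1 and 2, and 6.33% and 6.66% in Zscan4 OE 1 and 2. These argue against a loss confined to the highest level, a reading made after the values were seen. The lowest level, with shares of 3.03% and 4.08% against 2.8% and 3.0%, was past the bound set beforehand against this cause. That bound counted reads only, and the shift is smaller than the 0.43 between the 2 controls. A loss that spared only the lowest level was therefore left open, after the result was seen. An effect of Zscan4 itself is confounded with the cultures and stays untested.

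Reads at 2-cell-stage genes made up a larger share in Zscan4 OE. The 2 genes of most reads, Nelfa and Patl2, do not carry the difference, since without them the ratio was 1.46. The 3 genes picked for the largest excess, Zfp750, Patl2 and Pramel6, held 69.9% of the difference. Without these 3 the ratio was 1.17 (21.7 and 18.9 RPM in the controls, 23.3 and 24.3 in Zscan4 OE). Removing genes picked in this way lowers the ratio of any list, and random lists were not treated so, so whether the excess was unusually uneven was not tested. A signal over background that moves these genes as much as housekeeping genes is argued against by the 2 controls. They differed 0.974-fold at these genes, from 26 and 73 reads, and 1.91-fold at housekeeping genes. With so few reads a weaker effect of such a signal was left open. The comparison of the controls replaced the housekeeping ratio between groups, 1.16, once both had been seen. Chance stays open, as 98.3% of 10000 random lists of like depth had a lower ratio and this was 1 of 23 lists looked at, so an opening of these genes by Zscan4 is a hypothesis only.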
